A study of Mus musculus with 9 samples.

How the data were processed

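Messenger RNA was sequenced from mouse regulatory T cells (Tregs) of the BALB/c strain, marked by a Foxp3-linked green fluorescent protein and transduced with an orthogonal IL-2 receptor beta chain that carries a human EGFR tag. The growth protocol label describes another assay, a co-culture of naive T cells with such Tregs, so the culture given here rests on the treatment protocol label alone. Per that label, the cells were cultured with CD3/CD28 beads and 1000 IU/mL human IL-2 for 48 hours, isolated magnetically by the tag, and kept overnight without IL-2. They were then left without IL-2, or given 20000 IU/mL wild-type (WT) IL-2 or 2000000 IU/mL orthogonal (ortho) IL-2, for 4 hours. Each of the 3 groups has 3 libraries, prepared with a kit for mRNA and sequenced on an Illumina instrument. The labels do not say that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

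Each deposited table holds 31682 RefSeq transcripts of 23992 gene symbols. Per the file headers, its values are raw read counts and RPKM (reads scaled by transcript length and library depth). In each table the RPKM values deposited by the authors equal the reads divided by transcript length and by a whole number. This number is single for each library and is here called the RPKM divisor. It also counts reads outside the transcript taken for each gene, here called reads outside genes. These can lie in introns or in other transcripts of the same genes. Per the submitters' processing notes, Bowtie2, TopHat2, SAMtools 0.1.8, bedtools 2.25.0 and edgeR were used with the mm10 build. Their roles, the read counter, the annotation release and the use of strand are not given in the sources used here. Since strand use is not given, reads of overlapping or antisense genes cannot be told apart. Of the 220 genes named, 74 overlap another annotated gene on either strand, 19 of them on the same strand, and their values are uncertain to that extent. Reads of ribosomal protein genes and of Gapdh can be shared with their pseudogene copies, so these values are uncertain too.

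Before the data were examined, the groups, comparisons, tests, gene lists, the rule for naming genes and most alternatives were fixed. The design assumed RPKM values tested with limma, and named edgeR on counts as the main test should the tables hold raw counts, which they did. The transcript with the most reads stood for each of the 4343 symbols with several transcripts. Over all 23992 symbols, including those with a single transcript, the transcript taken was also the longest for 23425. Genes with an RPKM of at least 1 in at least 3 of the 9 libraries were tested, which left 10702 genes. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group means as terms over all 9 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are TMM-scaled ratios, levels are TMM-scaled depth-scaled counts (CPM), and errors of log2 fold changes are standard errors (SE) from the F statistic. The 95% intervals of the difference between ortho and WT IL-2 used a t distribution and a spread estimated over all 9 libraries. For 122 genes whose p-value edgeR raises to its Poisson bound, the wider error that p implies was used.

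The rule for named genes took, in each comparison, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, up to 4 members with the smallest p from each gene list, and a fixed set of 21 IL-2 pathway and Treg genes whatever their values. The 31 gene lists hold 871 symbols, of which 863 were in the tables (10 under an older symbol) and 718 were tested. They are IL-2/STAT5-induced genes, IL-2-repressed genes, FOXO/KLF2 quiescence genes, Treg identity genes, cytokine receptors, JAK/STAT components with SOCS regulators, ERK pathway feedback genes, immediate early genes, cytokine and effector genes, T cell lineage transcription factors, homing molecules, inhibitory and costimulatory receptors, BCL2 family genes, p53 targets, G1/S genes, G2/M genes, MYC targets with ribosome biogenesis, ribosomal proteins, glycolysis, cholesterol and fatty acid synthesis, amino acid and ATF4 genes, oxidative phosphorylation, unfolded protein response, type I interferon response, glucocorticoid and hypoxia response, B cell markers, myeloid markers, CD8 and NK cell markers, erythroid and stromal markers, T cell core genes and housekeeping genes. Lists were tested against all other genes with camera in limma 3.58.1, at a preset correlation of 0.01 between members, with adjustment over 93 tests. The test was repeated with an estimated correlation.

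Depth was 16581624 to 58182835 reads in genes per library, at which 3 reads, taken as the floor, correspond to 0.0516 to 0.181 CPM. Such floors cover counting error only. Coordinates are those of GRCm38, matched for 23763 symbols (99.0%). Transcript sequences of the GENCODE M21 annotation gave GC content. They also gave repeated sequence, defined as 20-base words found in the transcripts of at least 100 genes. A gene counted as holding repeats when at least 40 bases of its transcript were covered. The comparisons of ortho and WT IL-2 with no IL-2 share the no IL-2 libraries. To allow for this, 20 simulations of unchanged groups gave the correlation that sharing produces when genes vary independently. Trends of a library over many genes were not simulated. The fit was tested on simulated counts in which 200 of 10702 genes were changed. It recovered 78% of genes changed 1.5-fold and 92% of those changed 2-fold for WT against no IL-2, 74% and 92% for ortho against no IL-2, and 76% and 92% for ortho against WT IL-2. At 1.25-fold these shares were 20%, 18% and 16%. Unchanged genes made up 6 of 150, 4 of 145 and 22 of 163 calls, the last above the 5% that the threshold allows on average. These simulated counts held few changed genes, with rises and falls in equal number, and no trends of a library over many genes. In the data, 47.9% and 56.0% of genes were called against no IL-2 with WT and ortho IL-2. The shares above may therefore not hold for the data.

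The alternatives fixed in advance were other filters on low values, other scalings, DESeq2 1.42.0, limma on log2(RPKM + pseudocount) with pseudocounts of 1, 0.1 and 2 and in several variants, only the groups compared, the replicate number as a block, and leaving out each library. Further alternatives were chosen after seeing the data: the longest transcript, the RPKM divisor as library size, library totals, the share of reads outside genes as a covariate, leaving out genes that hold repeats, and offsets for GC content. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The human EGFR tag and the transduced receptor have no entry of their own in the tables, so reads of Il2rb can come from the endogenous gene and from the transduced chain.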

Results

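The transcriptomes of Tregs carrying an orthogonal IL-2 receptor beta chain were measured by RNA-seq after 4 hours without IL-2, with WT IL-2 or with ortho IL-2, in 3 libraries per group. IL-2 is the growth factor on which Tregs depend, and an orthogonal cytokine is an engineered form meant to act on the engineered receptor only. The series asks whether such a cytokine and receptor pair can expand Tregs selectively for transplantation tolerance. Reads in genes numbered 30213895, 26973536 and 16581624 in the no IL-2 libraries, 38797874, 33499391 and 31912919 in the WT IL-2 libraries, and 37497976, 21695631 and 58182835 in the ortho IL-2 libraries. The ortho IL-2 dose in IU/mL was 100 times the WT dose, so the responses were compared at unmatched doses.

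The libraries had the profile of T cells. Cd4, whose transcript holds repeats, reached 656 ± 15.4 CPM and Foxp3, the transcription factor that defines Tregs, 524 ± 9.58 CPM in the no IL-2 group (SD, n = 3). Few markers of other cell types were abundant enough to be tested: 5 of 14 B cell markers, 2 of 24 myeloid markers, 3 of 17 CD8 T and NK cell markers and 2 of 22 erythroid, platelet and stromal markers. Over the 500 most variable genes, the first principal component held 78.5% of the variance and the next 13.4%. The biological coefficient of variation was 5.31% within the no IL-2 group, 10.7% within the WT IL-2 group and 10.3% within the ortho IL-2 group, and 5.22%, 6.93% and 7.89% with GC offsets. Reads outside genes, as defined above, can lie in introns or in other transcripts of the same genes. They made up 40.5% ± 2.43 of the RPKM divisor without IL-2, 31.7% ± 2.96 with WT IL-2 and 29.4% ± 3.64 with ortho IL-2 (SD, n = 3 each). This share was higher in the 3 no IL-2 libraries than in the 6 stimulated ones (two-sided exact permutation p = 0.0238).

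**Figure D1:**
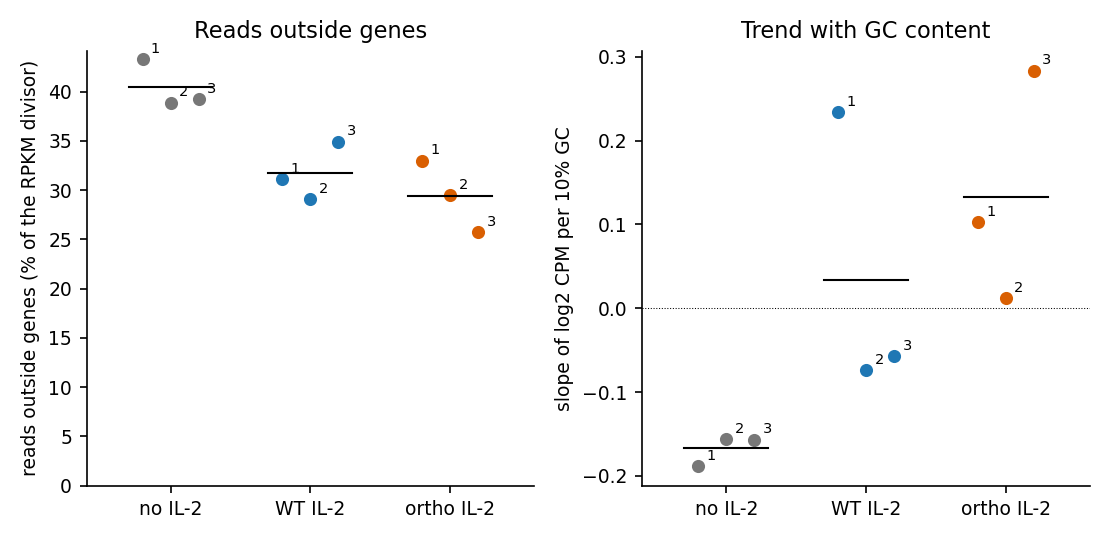
Share of reads outside the transcript taken for each gene, as percent of the RPKM divisor, for each of the 9 libraries. The other panel gives the slope of log2 expression with transcript GC content (log2 per 10 percentage points of GC). The share lies between 38.9% and 43.3% without IL-2 and between 25.7% and 34.9% in the stimulated libraries, and the slope reaches 0.23 in WT IL-2 replicate 1 and 0.28 in ortho IL-2 replicate 3.

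The first comparison, WT IL-2 against no IL-2, shows what the natural cytokine does in these cells. Il2ra encodes the alpha chain of the high-affinity IL-2 receptor (chromosome 2, 11642792 to 11693194, GRCm38). It rose 4.11-fold from 1217 ± 9.73 to 4994 ± 145 CPM (SD, n = 3, edgeR adjusted p = 2.69e-09). Cish and Socs1, inhibitors of cytokine receptor signalling that STAT5 induces, rose 7.73-fold (412 ± 61.9 against 53.4 ± 2.36 CPM) and 20.6-fold (115 ± 32 against 5.79 ± 1.7 CPM). The cytotoxic protease gene Gzmb rose 8.41-fold, the growth regulator Myc 5.48-fold and the survival gene Bcl2, whose transcript holds repeats, 4.70-fold. The largest falls included Bcl6, a repressor that drives the follicular helper programme (chromosome 16, 23965050 to 23988866), from 108 ± 2.96 to 24.4 ± 1.11 CPM. Another was Il7r, the IL-7 receptor alpha chain, whose transcript holds repeats, from 785 ± 12.3 to 218 ± 30.1 CPM.

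**Figure D2:**
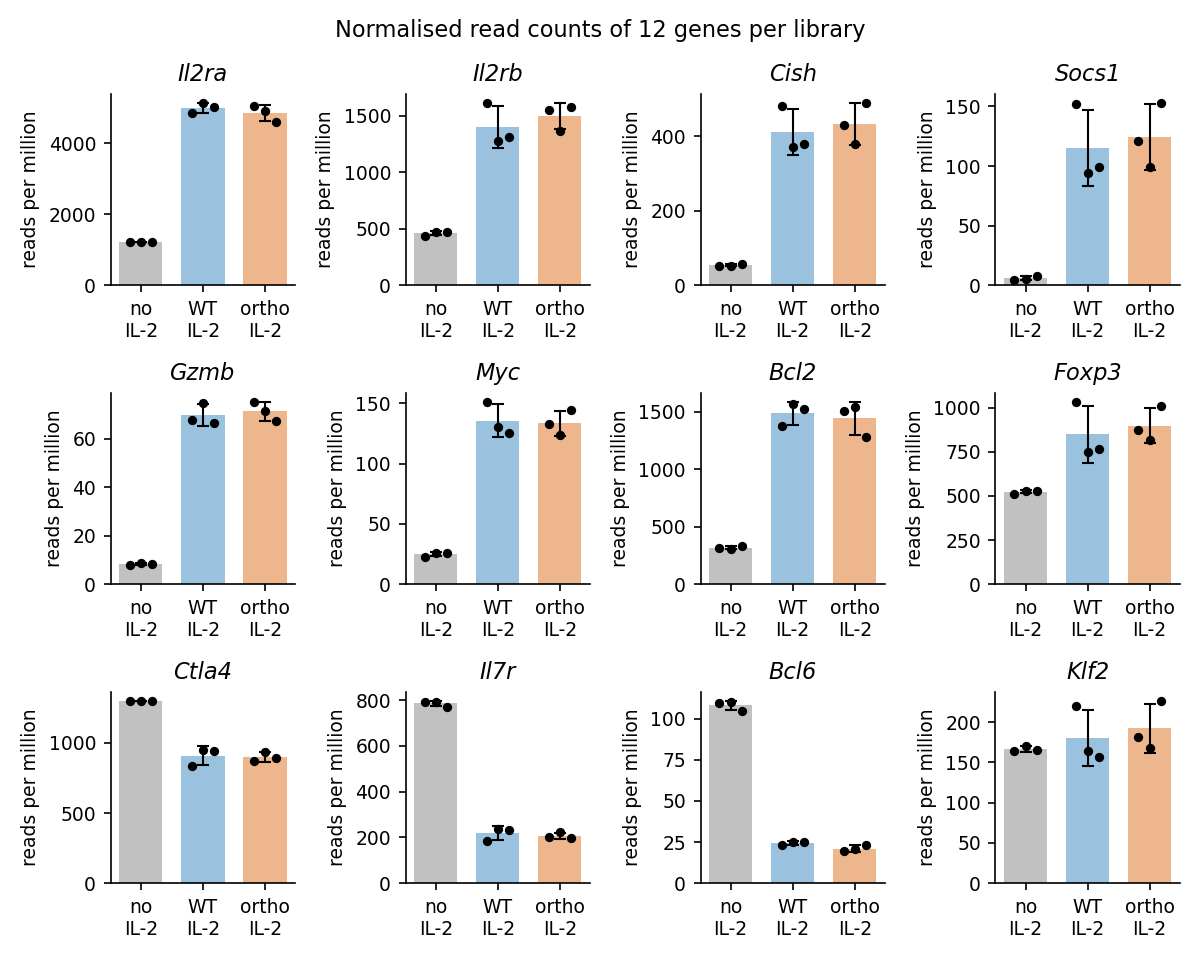
Expression of 12 genes in CPM for each library, with bars at the group mean and error bars of 1 SD (n = 3 per group). Il2ra, Cish, Socs1, Myc, Bcl2 and Gzmb lie higher, and Il7r and Bcl6 lower, in every stimulated library than in every library without IL-2.

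Among 33 IL-2/STAT5-induced genes tested, 26 were higher, 3 lower and 4 not called, and the counts adjusted over the list alone were 26 and 3 (camera adjusted p = 4.2e-50). Members included Lta, a lymphotoxin gene, from 16.1 ± 2.13 to 270 ± 24.3 CPM, and, both holding repeats, the costimulatory receptor gene Tnfrsf9 at 3.51-fold and Socs2 at 2.91-fold. Of 20 IL-2-repressed genes, 18 were lower, 0 higher by edgeR and 2 not called, with 18 lower and 0 higher adjusted over the list alone (camera adjusted p = 3.37e-21). They included the IL-6 receptor gene Il6ra (log2 fold change -0.83, SE 0.04), the antiproliferative gene Btg2 (-0.98, SE 0.04) and Pik3ip1, an inhibitor of PI3 kinase (-1.10, SE 0.04). FOXO/KLF2 quiescence genes fell in 20 of 24 cases, with 1 higher and 3 not called and the same 20 and 1 adjusted over the list alone (camera adjusted p = 2.32e-16). Sesn1, a stress-induced inhibitor of mTORC1, fell by 1.31 and the proapoptotic gene Bcl2l11, whose transcript holds repeats, fell by 1.20 on the log2 scale. Klf2 itself was not called (log2 fold change 0.11, SE 0.14, adjusted p = 0.525) but was called lower, at -0.12, with GC offsets.

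Treg identity genes moved both ways, with 15 higher, 9 lower and 4 not called among 28, and 16 and 9 adjusted over the list alone (camera, higher, adjusted p = 3.64e-08). Foxp3 rose 1.62-fold (524 ± 9.58 to 849 ± 161 CPM, adjusted p = 0.000998), although its reads overlap those of the noncoding gene Flicr and it was not called with the share of reads outside genes as a covariate (adjusted p = 0.0653). Gpr83, a receptor typical of Tregs, rose 6.72-fold, Tnfrsf18 (GITR) 2.12-fold and Icos, a costimulatory receptor, 1.36-fold. In contrast, Ctla4, an inhibitory receptor central to Treg function, fell from 1299 ± 2.07 to 909 ± 66.5 CPM, Ikzf2 (Helios), whose transcript holds repeats, fell by 0.29 and the integrin gene Itgae by 0.82 on the log2 scale. Ikzf2 was not called on unscaled RPKM (-0.08), nor without no IL-2 replicate 1 or WT IL-2 replicate 1. The 28 cytokine receptor genes gave 8 higher, 10 lower and 10 not called, with 8 and 10 adjusted over the list alone, and no shift against other genes (camera, higher, adjusted p = 0.977). Their median log2 fold change was -0.02, with the opposite sign to their mean of 0.08, and it was 0.18 on unscaled RPKM. Il2rb rose 3.05-fold (460 ± 19.1 to 1402 ± 184 CPM), a value that cannot separate the endogenous gene from the transduced chain. Il2rg, the shared gamma chain, fell by 0.13 on the log2 scale (SE 0.04, adjusted p = 0.026) but lay at 0.08, not called, on unscaled RPKM. It was also not called without no IL-2 replicate 2 or 3 or WT IL-2 replicate 1 or 3. Mouse Egfr was too low to be tested, with 8 to 33 reads per library over the 9 libraries.

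JAK/STAT and SOCS genes gave 11 higher, 7 lower and 9 not called among 27, with 12 and 7 adjusted over the list alone (camera, higher, adjusted p = 0.065; the median of 0.05 changed sign with quantile normalization). Socs3 rose 4.10-fold, while the transcription factor genes Stat5a, which overlaps Stat3, and Stat5b fell by 0.43 and 0.67, Stat5a not being called on unscaled RPKM (-0.21). Cytokine and effector genes gave 13 higher, 1 lower and 6 not called among 20, with 13 and 1 adjusted over the list alone (camera adjusted p = 4.14e-16). Lif, an IL-6 family cytokine, rose 8.31-fold and Tnf 6.75-fold. ERK feedback genes gave 9 higher, 1 lower and 3 not called among 13, likewise 9 and 1 adjusted over the list alone (camera adjusted p = 1.14e-05, and adjusted p = 0.086 with an estimated correlation). The ERK phosphatase gene Dusp6 rose 5.04-fold, the inhibitor gene Spred1 rose by 2.81 on the log2 scale (SE 0.13), and Dusp10, a phosphatase of p38 and JNK whose transcript holds repeats, fell by 1.56 on the log2 scale.

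Among genes of cell growth, MYC targets and ribosome biogenesis genes gave 54 higher, 0 lower by edgeR and 10 not called among 64, with 54 and 0 adjusted over the list alone (camera adjusted p = 4.09e-19). Eif5a, a translation factor, rose 2.63-fold and the nucleolar methyltransferase gene Nop2 2.53-fold. Amino acid transport, serine synthesis and ATF4 genes gave 25 higher, 2 lower and 6 not called among 33, with 25 and 2 adjusted over the list alone (camera adjusted p = 3.25e-13). Aldh18a1, an enzyme of proline synthesis, rose 3.03-fold and Psat1, an enzyme of serine synthesis, 2.65-fold. Glycolysis genes rose in 18 of 22 cases, with 1 lower and 3 not called and 19 and 1 adjusted over the list alone (camera adjusted p = 0.00535, and adjusted p = 0.507 with an estimated correlation). Changes were small, at 1.28-fold for Pgam1 and 1.21-fold for Pgk1. Of 53 ribosomal protein genes, 2 were higher, 0 lower by edgeR and 51 not called, with 0 called adjusted over the list alone (camera, higher, adjusted p = 0.872; median 0.03, or -0.02 with quantile normalization).

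Cell cycle genes moved both ways. Of 57 G1/S and S phase genes, 16 were higher, 7 lower and 34 not called, with 15 and 6 adjusted over the list alone (camera, higher, adjusted p = 0.33). The G1 regulators Ccnd2 and Cdk6, whose transcripts hold repeats, rose 2.82-fold and 3.74-fold, and Ccnd3, which overlaps Bysl, 2.85-fold. Of 53 G2/M genes, 9 were higher, 12 lower and 32 not called, with 9 and 6 adjusted over the list alone (camera, lower, adjusted p = 0.208; median -0.09, or 0.12 on unscaled RPKM). Among them, the condensin gene Smc4 fell from 3848 ± 42.8 to 2143 ± 291 CPM and the centromeric histone gene Cenpa by 0.47 on the log2 scale.

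In all, 2675 genes were higher and 2447 lower with WT IL-2, 47.9% of the 10702 tested, and 373 and 129 of these changed at least 2-fold. The groups did not overlap for 58.8% of genes, against 10% by chance. The largest rises beyond those above were in Emilin2 (22.1-fold), an extracellular matrix gene, the growth factor gene Hbegf (19.1-fold), Drc1 (14.2-fold), S1pr3 and Creb5, both holding repeats (13.8-fold and 11.9-fold), and, from 2 to 6 reads per library without IL-2, Tgm1 and Prok1 (29.8-fold and 20.5-fold). Mir6974 lies within Lta and had 1 read without IL-2 in all, so no fold change is given. The largest falls also included Fam101b and Epas1, both holding repeats (log2 fold changes -2.69 and -1.75), Tktl1 (-2.02), Tdrp (-1.96), the G protein regulators Gng4 (-1.78) and Rgs2 (-1.72), Rin2 (-1.71), and Mir7675 (-1.80), at 4 to 16 reads per library. On unscaled RPKM, limma placed the median gene at 0.19 and called 83.7% of changed genes higher, against 52.2% here, with 341 higher and 23 lower by at least 2-fold (604 and 64 by edgeR with the RPKM divisor). Without WT IL-2 replicate 3, the number lower by at least 2-fold was 201 in place of 129.

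The next comparison, ortho IL-2 against no IL-2, shows what the engineered cytokine does in these cells. All libraries came from transduced cells, so which receptor it acted through was not tested. Il2ra rose 3.98-fold (1217 ± 9.73 to 4845 ± 221 CPM, SD, n = 3; edgeR adjusted p = 3.09e-09), Cish 8.14-fold and Socs1 22.3-fold (to 124 ± 27.3 CPM). Gzmb rose 8.62-fold, Myc by 2.43 on the log2 scale (SE 0.09), Lta to 271 ± 4.53 CPM, Il2rb 3.26-fold and Bcl2, holding repeats, 4.56-fold. Foxp3, overlapping Flicr, rose 1.72-fold to 899 ± 99.5 CPM (adjusted p = 0.000452, or 0.125 with the share of reads outside genes as a covariate) and Icos 1.32-fold, while Ctla4 fell to 900 ± 34.3 CPM. Bcl6 and Il7r, the latter holding repeats, fell with log2 fold changes of -2.36 and -1.93 (SE 0.07 and 0.09).

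Of the 33 IL-2/STAT5-induced genes, 26 were higher, 4 lower and 3 not called, with 26 and 4 adjusted over the list alone (camera adjusted p = 7.62e-49). Of the 20 IL-2-repressed genes, 1 was higher, 18 lower and 1 not called, with 1 and 18 adjusted over the list alone (camera adjusted p = 2.85e-20). FOXO/KLF2 genes gave 2 higher, 20 lower and 2 not called among 24, with 2 and 20 adjusted over the list alone (camera adjusted p = 2.72e-15). Treg identity genes gave 16 higher, 9 lower and 3 not called among 28, and again 16 and 9 adjusted over the list alone (camera, higher, adjusted p = 1.04e-07). Gpr83 rose 6.70-fold and Tnfrsf18 2.30-fold, and Ikzf2, holding repeats, fell by 0.35 on the log2 scale, but was not called on unscaled RPKM (-0.08). Cytokine receptor genes gave 9 higher, 11 lower and 8 not called among 28, with 9 and 11 adjusted over the list alone (camera, higher, adjusted p = 0.989; median 0.02, or -0.02 with GC offsets). Il2rg fell by 0.17 (SE 0.04, adjusted p = 0.00625) but lay at 0.10, not called, on unscaled RPKM. Klf2 was not called (0.21, SE 0.14, adjusted p = 0.218), but was called lower with GC offsets (-0.15) and higher on unscaled RPKM (0.46).

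JAK/STAT and SOCS genes gave 11 higher, 7 lower and 9 not called among 27, with 11 and 8 adjusted over the list alone (camera, higher, adjusted p = 0.0598). Socs2, holding repeats, rose 2.84-fold, Socs3 4.30-fold and the kinase gene Pim1 1.85-fold, and Stat5a and Stat5b fell by 0.34 and 0.63, Stat5a not being called on unscaled RPKM (-0.07). Cytokine and effector genes gave 14 higher, 1 lower and 5 not called among 20, with 14 and 1 adjusted over the list alone (camera adjusted p = 2.32e-16), among them Lif (8.94-fold) and Tnf (7.32-fold). ERK feedback genes gave 9 higher, 1 lower and 3 not called among 13, with 9 and 1 adjusted over the list alone (camera adjusted p = 1.42e-05, and adjusted p = 0.0939 with an estimated correlation), among them Dusp6 (5.24-fold) and Spred1 (6.72-fold).

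MYC targets and ribosome biogenesis genes gave 53 higher, 0 lower by edgeR and 11 not called among 64, with 54 and 0 adjusted over the list alone (camera adjusted p = 4.96e-17), among them Eif5a (2.64-fold) and Phb (2.63-fold), a mitochondrial scaffold protein. Amino acid and ATF4 genes gave 26 higher, 1 lower and 6 not called among 33, with 26 and 4 adjusted over the list alone (camera adjusted p = 1.01e-12), among them Aldh18a1 (3.08-fold) and the alanyl-tRNA synthetase gene Aars (2.00-fold). Glycolysis genes were higher in 21 of 22 cases and lower in 1, with 21 and 1 adjusted over the list alone (camera adjusted p = 0.000148, and adjusted p = 0.359 with an estimated correlation), at 1.35-fold for Pkm and 1.27-fold for Pgk1. Of 53 ribosomal protein genes, 8 were higher, 0 lower by edgeR and 45 not called, with 0 called adjusted over the list alone (camera, higher, adjusted p = 0.616; median 0.06, or -0.02 with quantile normalization). Rps10 was 1.19-fold higher (log2 fold change 0.25, adjusted p = 0.0134), but lay at -0.07 with GC offsets and was not called without no IL-2 replicate 1. Of 57 G1/S genes, 16 were higher, 7 lower and 34 not called, with 15 and 7 adjusted over the list alone (camera, higher, adjusted p = 0.329; median 0.03, changing sign with quantile normalization). Of 53 G2/M genes, 9 were higher, 26 lower and 18 not called, with 9 and 26 adjusted over the list alone (camera, lower, adjusted p = 0.0764; median -0.14, or 0.14 on unscaled RPKM), with Smc4 at -0.95 and Hmmr, a mitotic spindle gene, at -0.41, or -0.12 and not called on unscaled RPKM.

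**Figure D3:**
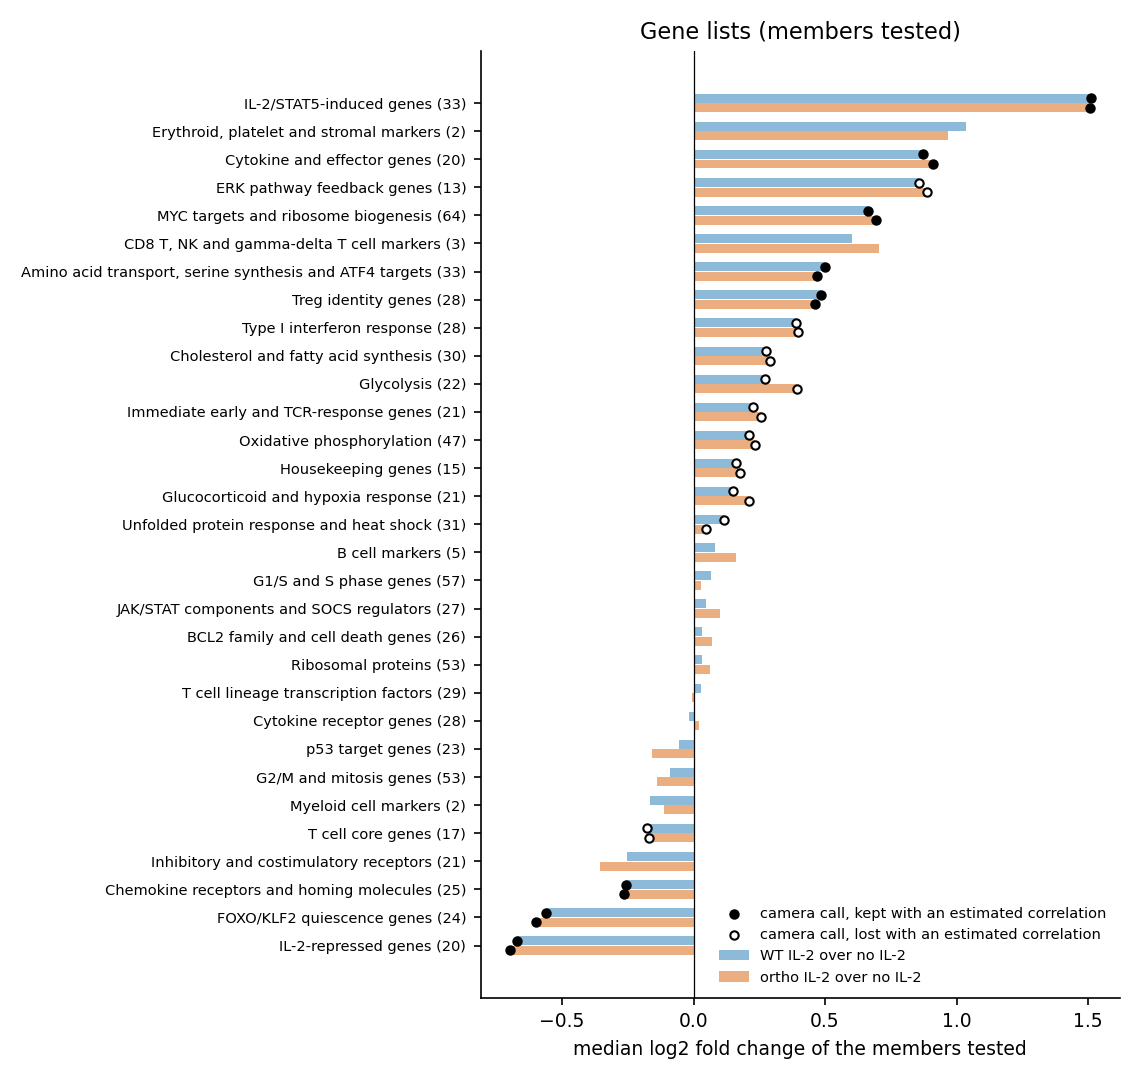
Median log2 fold change of the tested members of each gene list in WT IL-2 and ortho IL-2 against no IL-2 (edgeR, TMM scaling, n = 3 libraries per group). The medians of IL-2/STAT5-induced genes are 1.51 in both comparisons and those of IL-2-repressed genes -0.67 and -0.70, while those of p53 target, G2/M, myeloid marker and T cell core genes change sign in both on unscaled RPKM.

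In all, 3054 genes were higher and 2936 lower with ortho IL-2, 56.0% of those tested, and 410 and 261 changed at least 2-fold. The groups did not overlap for 66.1% of genes, against 10% by chance. The largest rises beyond those above were in Tgm1 and Prok1 (34.6-fold and 20.5-fold, from 2 to 6 reads per library without IL-2), Emilin2 (23.6-fold), Hbegf (18.6-fold), Drc1 (14.5-fold), S1pr3, holding repeats (13.4-fold), and Mcf2l (11.6-fold), with Mir6974 again within Lta. The largest falls also included Fam101b (-2.66, holding repeats), the prolactin receptor gene Prlr (-2.03), Rbpms2 (-2.03), Tdrp (4.01-fold lower), Mir7675 (-2.07, at 3 to 16 reads per library) and Scarna10, within Ncapd2 and with 4 reads in all with ortho IL-2. C230091D08Rik (-2.10), Ptk6 (-1.97) and Tmem82 (-1.93) varied within groups, and their values were 0.43, 0.68 and 0.79 with the share of reads outside genes as a covariate. Ptk6 and Tmem82 were not called without no IL-2 replicate 1, nor Tmem82 without ortho IL-2 replicate 2 or 3. Genes that hold repeats made up 48.3% of the genes lower by at least 2-fold, and 28.7% with WT IL-2, but 49 of 410 and 49 of 373 of those higher by at least 2-fold. On unscaled RPKM, limma placed the median gene at 0.25 and called 85.9% of changed genes higher, against 51.0% here, with 430 higher and 72 lower by at least 2-fold (763 and 166 by edgeR with the RPKM divisor). The number lower by at least 2-fold was 150 without no IL-2 replicate 1, 152 without ortho IL-2 replicate 3, and 116 with the share of reads outside genes as a covariate, in place of 261. Without a filter on low values, over 19806 genes, edgeR placed more genes lower than higher by at least 2-fold with ortho IL-2 (934 against 671). With WT IL-2 these were 342 and 576.

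With an estimated correlation between members, camera called 8 lists in each of these comparisons. In both they were the lists of IL-2/STAT5-induced, IL-2-repressed, FOXO/KLF2, Treg identity, cytokine and effector, homing, MYC and ribosome biogenesis, and amino acid and ATF4 genes (largest adjusted p = 0.0325 with WT IL-2 and 0.0419 with ortho IL-2).

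The responses to WT and ortho IL-2 were then set side by side over all genes. Across the 10702 genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.972 and a Spearman rho of 0.965, against 0.410 and 0.305 for simulated unchanged groups sharing the no IL-2 libraries. Their covariance was 0.281, against 0.00973 simulated. The simulated genes varied independently, without trends over genes such as that with GC content, so the simulated values may be too low. Of the genes higher with WT IL-2, 2533 were higher with ortho IL-2 as well, where independent lists would share 763, and of those lower 2296 were lower as well, where independent lists would share 671. By edgeR, 0 genes were called in opposite directions. Since 3 control libraries cannot be split with 2 or more on each side, part of the excess may come from the shared controls. Of the 4829 genes called in both, 64.2% had the larger change with ortho IL-2, with a median ratio of log2 fold changes of 1.06. The number of calls did not keep this order throughout. Without ortho IL-2 replicate 3, edgeR called 2544 genes higher and 2356 lower with ortho IL-2, against 2748 and 2596 with WT IL-2. A group with fewer libraries can also yield fewer calls. With the share of reads outside genes as a covariate, the counts were 1067 and 765 against 1388 and 1063. All other settings called more genes with ortho than with WT IL-2. The fold changes over genes followed transcript GC content more closely with ortho than with WT IL-2 (Spearman rho 0.436 and 0.317). Whether the larger changes depend on it was not tested.

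**Figure D4:**
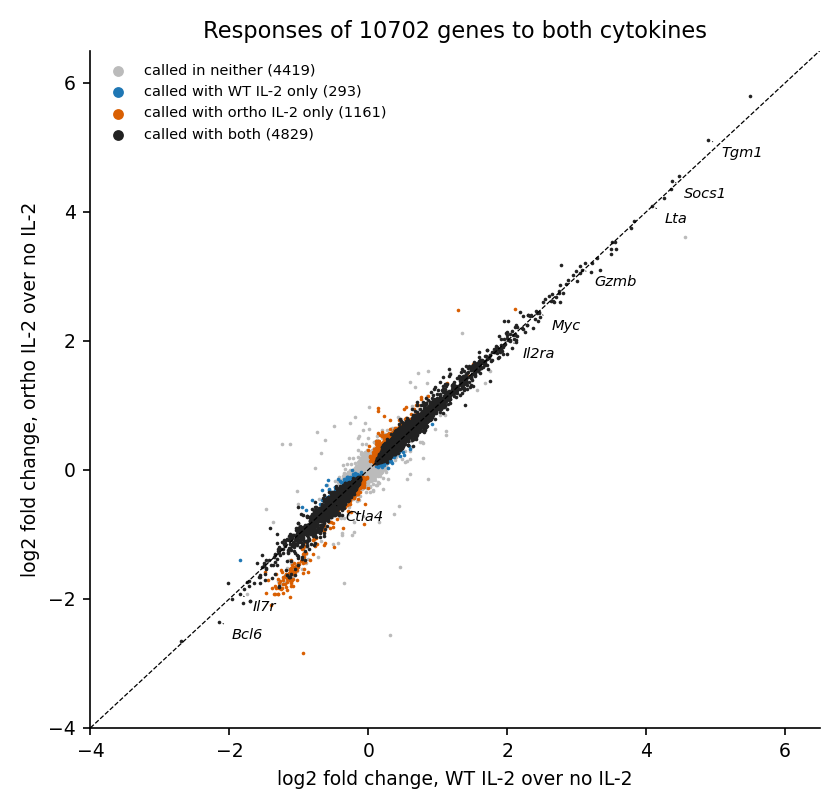
Log2 fold change against no IL-2 of each of the 10702 tested genes, with WT IL-2 on the horizontal and ortho IL-2 on the vertical axis (edgeR, n = 3 per group). The 4829 genes called in both lie along the diagonal in the same direction, and 293 were called with WT IL-2 alone and 1161 with ortho IL-2 alone. By edgeR, 0 genes were called between the cytokines.

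The last comparison, ortho against WT IL-2, asks whether the cytokines differ directly at the doses used. Il2ra was 0.970-fold in ortho relative to WT IL-2 (95% interval 0.901 to 1.04), Il2rb 1.07-fold (0.928 to 1.23) and Foxp3 1.06-fold (0.879 to 1.27). Gzmb was 1.02-fold (0.928 to 1.13), Ctla4 0.990-fold (0.906 to 1.08), Icos 0.971-fold (0.905 to 1.04), Bcl2 0.969-fold (0.860 to 1.09) and Myc 0.985-fold (0.865 to 1.12). Of the signalling inhibitors, Cish had a log2 difference of 0.07 (-0.18 to 0.32) and Socs1, more variable, of 0.11 (-0.36 to 0.59). The smallest p among the named genes was that of Bcl6, at 0.865-fold (0.776 to 0.963; edgeR adjusted p = 0.909), which did not pass the correction. Il2ra, Ctla4, Icos, Bcl2 and Myc lay on the other side of 1 on unscaled RPKM.

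**Figure D5:**
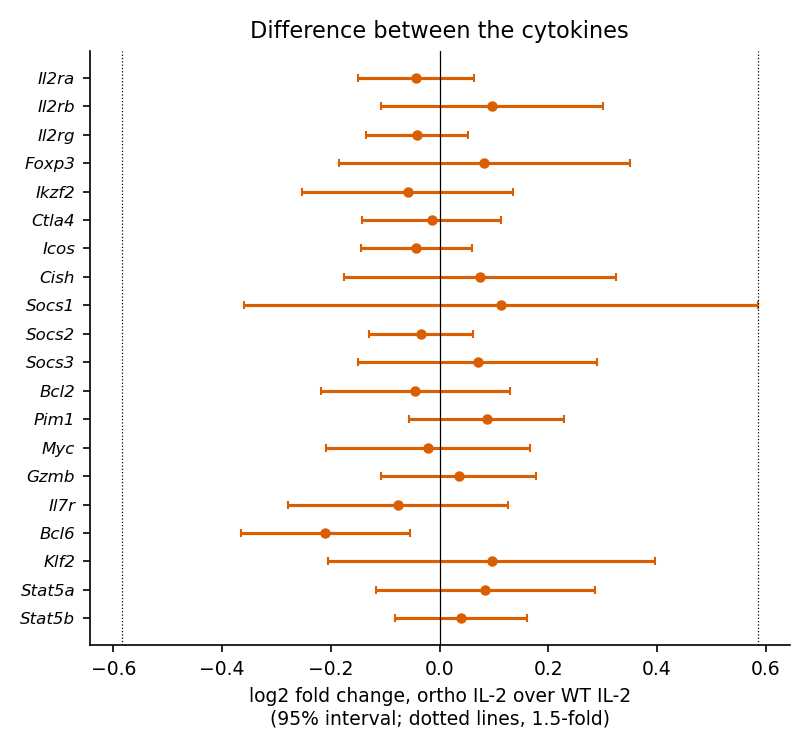
Fold difference of ortho against WT IL-2 with its 95% interval for 20 IL-2 pathway and Treg genes on a log axis (edgeR, n = 3 per group), with dotted lines at 1.5-fold in each direction. Bcl6, at 0.865 (0.776 to 0.963), has an interval clear of 1, and that of Socs1, from 0.779, reaches the upper dotted line.

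By edgeR, 0 of 10702 genes were called in either direction, with 149 at a raw p under 0.05 and a smallest adjusted p of 0.909. This is fewer than the share of 0.05 that chance would give for independent genes. The count of 0 alone therefore does not show that the cytokines acted alike. The variation within the WT and ortho IL-2 groups was 10.7% and 10.3%, but 6.93% and 7.89% with GC offsets. With these offsets 229 genes had a raw p under 0.05, and again 0 were called. DESeq2 called 0, with 114 at a raw p under 0.05, and limma on log2(RPKM + 1) called 0, with 126. The groups did not overlap for 4.65% of genes, against 10% by chance. The intervals lay within 1.5-fold in both directions for 9980 genes (93.3%) and within 2-fold for 97.0%. Among the 702 genes that responded at least 2-fold to either cytokine, these shares were 69.7% and 81.5%, so a difference of 1.5-fold was not excluded for the rest. Without WT IL-2 replicate 1 the number at a raw p under 0.05 was 2616 in place of 149, above the share of 0.05. Still 0 were called by edgeR, with a smallest adjusted p of 0.173. The number at a raw p under 0.05 thus depended on a single library.

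Over genes, the log2 differences between ortho and WT IL-2 followed transcript GC content (Spearman rho 0.673), so small shifts of lists may go with it. As a group, the 22 glycolysis genes were placed slightly higher with ortho than WT IL-2, at a median log2 difference of 0.09, or 0.06 with GC offsets. Of these, 0 members were called by edgeR and 0 adjusted over the list alone (camera adjusted p = 1.51e-10, and adjusted p = 0.153 with an estimated correlation). Aldoc, an aldolase, was 1.14-fold, Gapdh 1.11-fold, Pkm 1.09-fold and Tpi1 1.09-fold, each with an edgeR adjusted p of 0.909. G2/M genes had a median of -0.05 (camera adjusted p = 0.00271, and adjusted p = 0.467 with an estimated correlation). This median was 0.01 on unscaled RPKM and -0.02 with GC offsets. Camera also called ribosomal proteins (median 0.03, changing sign with quantile normalization; adjusted p = 0.0197), oxidative phosphorylation (0.03; adjusted p = 0.032), glucocorticoid and hypoxia genes (0.03; adjusted p = 0.0385) and cytokine and effector genes (0.06; adjusted p = 0.0444). For these the adjusted p = 0.622, 0.573, 0.334 and 0.334 with an estimated correlation, and in each of the lists 0 members were called by edgeR or adjusted over the list alone. With GC offsets the medians of these lists were 0.01, 0.01, 0.02 and 0.02. IL-2/STAT5-induced and IL-2-repressed genes had medians of 0.04 and -0.01 (0.05 on unscaled RPKM for the latter), with adjusted p = 0.202 and 0.819.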

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

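The longest transcript, the RPKM divisor, the covariate, leaving out genes that hold repeats, and GC offsets were chosen after seeing the data. In each alternative run, 0 genes were called between ortho and WT IL-2 by edgeR, DESeq2 or limma (149 at a raw p under 0.05 by edgeR as reported). Against no IL-2, edgeR called 2675 genes higher and 2447 lower with WT IL-2 and 3054 and 2936 with ortho IL-2. DESeq2 gave 2649 and 2620, and 2988 and 3065. Leaving out each library gave 2173 to 2748 and 1895 to 2596 with WT IL-2, 2462 to 3387 and 2284 to 3247 with ortho IL-2, and 0 to 0 between the cytokines. GC offsets gave 3120 and 2940, and 3189 and 3146. The trend with GC content differs between the groups, so these offsets can take out part of a group difference by construction. The replicate numbers did not pair the libraries (mean correlation of same-number libraries 0.0002, range -0.66 to 0.44 over 9 pairs), and a fit with the replicate number as a block gave 2515 and 2273, and 2846 and 2806. On unscaled RPKM the split moved to higher genes. The counts, WT then ortho, higher then lower, were 4459, 867, 5599 and 922 with limma on log2(RPKM + 1), 4495, 839, 5605 and 914 with a pseudocount of 0.1, 4418, 871, 5594 and 925 with 2, 4450, 870, 5590 and 918 without the intensity trend, and 4452, 1023, 5796 and 1224 with library weights. With the RPKM divisor as library size edgeR gave 4630, 895, 5707 and 946. The divisor counts reads outside genes, which are a smaller share in the stimulated libraries. Its construction therefore moves the median gene up, to 0.22 with WT and 0.29 with ortho IL-2. Il2rg, called lower as reported, turned positive in these settings without being called (adjusted p = 0.279 to 0.681): 0.0824, 0.0828 and 0.0819 with WT IL-2 in limma with pseudocounts of 1, 0.1 and 2, 0.0824 without the intensity trend, 0.10 with ortho IL-2 in each of these, 0.0489 and 0.0310 with library weights, and 0.0827 and 0.11 with the divisor. With the share of reads outside genes as a covariate, the counts were 1388, 1063, 1067 and 765, and C230091D08Rik, Ptk6 and Tmem82, lower with ortho IL-2 as reported, reversed to 0.43, 0.68 and 0.79. Foxp3 was then not called (0.53 with WT and 0.56 with ortho IL-2, adjusted p = 0.0653 and 0.125), nor was Ikzf2 (-0.10 in both). The covariate differs between the groups, so it takes up part of the group difference by construction. With GC offsets Klf2, not called as reported, reversed to called falls of -0.12 with WT and -0.15 with ortho IL-2 (adjusted p = 0.024 and 0.00849), Rps10 to -0.0677 with ortho IL-2, and the amino acid and ATF4 list between the cytokines to lower (adjusted p = 0.0354, against 0.819), and the cause was not tested. The correlation of the responses over genes, 0.972 as reported, was 0.747 without a filter on low values and 0.748 with DESeq2 size factors and no filter, settings that test 19806 genes in place of 10702. It was 0.937 to 0.979 on leaving out each library, with 0.937 without WT IL-2 replicate 1 and 0.940 without ortho IL-2 replicate 1. Over all settings, values of named genes kept their direction and side of the threshold in 3646 cases with WT IL-2 (60 weaker, 48 stronger, 7 reversed) and 3718 with ortho IL-2 (72 weaker, 22 stronger, 11 reversed). Of the 18 list calls in each comparison with no IL-2, 16 and 17 held with GC offsets, out of 17 and 18 lists called there. All 18 held with the replicate block, where camera called 19 lists in each. Between the cytokines 2 of 6 held with GC offsets, and 6 further lists were called: interferon, inhibitory and costimulatory, homing and housekeeping genes higher, and MYC and amino acid genes lower.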

Other observations

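Cholesterol and fatty acid synthesis genes gave 17 higher, 4 lower and 9 not called among 30 with WT IL-2, with 17 and 4 adjusted over the list alone (camera adjusted p = 0.000766, and adjusted p = 0.131 with an estimated correlation), among them Elovl6, a fatty acid elongase holding repeats (4.62-fold). With ortho IL-2 they gave 16, 4 and 10, with 17 and 4 adjusted over the list alone (adjusted p = 0.000887, and adjusted p = 0.147 with an estimated correlation). Unfolded protein response genes gave 13 higher, 3 lower and 15 not called among 31 with each cytokine, with 13 and 3 adjusted over the list alone (adjusted p = 0.00825 and 0.02, and adjusted p = 0.0843 and 0.129 with an estimated correlation), led by the transcription factor gene Xbp1 (3.91-fold and 3.88-fold). Oxidative phosphorylation genes gave 23 higher and 24 not called among 47 with WT IL-2 and 30 and 17 with ortho IL-2, with 25 and 32 higher adjusted over the list alone (adjusted p = 0.0344 and 0.0164, and adjusted p = 0.573 and 0.514 with an estimated correlation). Type I interferon genes gave 15 higher, 2 lower and 11 not called among 28 with WT IL-2 and 18, 5 and 5 with ortho IL-2, with 16 and 2, and 18 and 5, adjusted over the list alone (adjusted p = 0.000887 and 0.000398, and adjusted p = 0.222 and 0.165 with an estimated correlation). Among them, Ifi35 rose 2.68-fold and 2.83-fold. Glucocorticoid and hypoxia genes gave 13 higher, 6 lower and 2 not called among 21, and 15, 6 and 0 by edgeR, with 13 and 6, and 15 and 6, adjusted over the list alone (adjusted p = 0.0424 and 0.0212, and adjusted p = 0.341 and 0.228 with an estimated correlation), led by the kinase gene Sgk1 (3.03-fold and 3.06-fold).

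Migration and lineage genes moved both ways. Homing molecules gave 3 higher, 14 lower and 8 not called among 25 with WT IL-2 and 5, 14 and 6 with ortho IL-2, with 5 and 14 adjusted over the list alone in both (camera adjusted p = 0.000342 and 0.000831). Their medians were -0.26 in both, or -0.03 with WT and 0.01 with ortho IL-2 on unscaled RPKM. The integrin gene Itga4 fell by 1.23 and 1.29 and the egress receptor gene S1pr1 by 0.64 and 0.67 on the log2 scale. Immediate early and TCR-response genes gave 10 higher, 6 lower and 5 not called among 21, and 11, 5 and 5, with 10 and 6, and 11 and 5, adjusted over the list alone (adjusted p = 0.0242 and 0.0133, and adjusted p = 0.468 and 0.417 with an estimated correlation). Fos rose 3.22-fold and 3.16-fold, while Tnfaip3, an inhibitor of NF-kappaB, fell by 0.95 and 0.93. Lineage transcription factors gave 10 higher, 13 lower and 6 not called among 29, and 11, 13 and 5, with 10 and 13, and 11 and 13, adjusted over the list alone. Camera placed them lower (adjusted p = 0.535 and 0.389) although the median with WT IL-2 was 0.03, and that with ortho IL-2, -0.01, was 0.25 on unscaled RPKM. Tcf7, which overlaps Skp1a, fell by 1.34 and 1.32 and Myb rose 4.39-fold and 4.24-fold. Inhibitory and costimulatory receptors gave 8 higher, 10 lower and 3 not called among 21, and 8, 11 and 2, with 9 and 10, and 8 and 11, adjusted over the list alone (camera, lower, adjusted p = 0.846, and higher, adjusted p = 0.999). Their medians were -0.25 and -0.35 against means of 0.06 and 0.10, and these medians were -0.04 and -0.08 on unscaled RPKM. Pdcd1, which encodes PD-1, fell by 1.21 and 1.16. BCL2 family genes gave 7 higher, 5 lower and 14 not called among 26, and 7, 6 and 13, with the same 7 and 5, and 7 and 6, adjusted over the list alone (higher, adjusted p = 0.505 and 0.509; median with WT IL-2 0.03, or -0.04 with GC offsets). Bcl2l1, which encodes BCL-XL, rose 3.02-fold and 3.10-fold. The p53 targets gave 4 higher, 8 lower and 11 not called among 23, and 6, 8 and 9, with 5 and 9, and 6 and 10, adjusted over the list alone (lower, adjusted p = 0.176 and 0.21; medians -0.05 and -0.16, or 0.15 and 0.10 on unscaled RPKM).

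Of 5 B cell markers tested, 1 was lower and 4 not called with WT IL-2, and 1 was higher, 1 lower and 3 not called with ortho IL-2, unaltered when adjusted over the list alone (camera adjusted p = 0.945 and 0.989; medians 0.08 and 0.16 against means of -0.07 and -0.03). The higher one was H2-Ab1 (0.42), not called with GC offsets (0.18), with the share of reads outside genes as a covariate (0.18) or without no IL-2 replicate 1. Vpreb3 fell from 1.06 ± 0.0515 to 0.541 ± 0.118 CPM with WT IL-2. Of 2 myeloid markers, Itgam, holding repeats, was lower with both cytokines, but not called by limma on unscaled RPKM (-0.22 and -0.19). Cst3 was higher with ortho IL-2 and not called with WT IL-2 (adjusted p = 0.0609 by edgeR, 0.0486 by DESeq2), and no difference between the cytokines was called (adjusted p = 0.909). The list had 1 higher and 1 lower adjusted over the list alone in both (lower, adjusted p = 0.846 and 0.937; medians -0.17 and -0.11, or 0.12 and 0.22 on unscaled RPKM). Of 3 CD8 T and NK cell markers, Gzma (2.42-fold and 2.37-fold) and Nkg7 (1.52-fold and 1.63-fold), which activated Tregs can express, were higher and Cd8b1, holding repeats, not called in both, with 2 higher adjusted over the list alone (adjusted p = 0.344 and 0.329). Of 2 erythroid, platelet and stromal markers, Epcam was higher (5.43-fold and 4.94-fold, from 2.76 CPM without IL-2) and Pecam1 lower in both, though not called on unscaled RPKM (-0.15 and -0.09), with 1 and 1 adjusted over the list alone (higher, adjusted p = 0.355 and 0.437). T cell core genes gave 3 higher, 10 lower and 4 not called among 17, and 4, 10 and 3, with 3 and 10, and 5 and 10, adjusted over the list alone (adjusted p = 0.02 and 0.0424, and adjusted p = 0.334 and 0.371 with an estimated correlation). Their medians were -0.18 and -0.17, or 0.04 and 0.11 on unscaled RPKM, and Cd28 fell by 0.84 and 0.93. Housekeeping genes gave 7 higher and 8 not called among 15 in both, with 7 higher adjusted over the list alone (adjusted p = 0.0424 and 0.0288, and adjusted p = 0.165 and 0.146 with an estimated correlation), with Tfrc at 2.07-fold and 2.01-fold.

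The tests of the patterns below were chosen after the results were seen, except those of upstream run-on, of equal depth and of other splits. Among 10216 genes, 97 varied within groups together with the share of reads outside genes (r of at least 0.9), and 77 of them were called lower with ortho IL-2 and 2 with WT IL-2. The log2 fold changes of these genes were negative with both cytokines, from -1.47 to -0.63 with WT IL-2 and from -2.10 to -1.07 with ortho IL-2. By edgeR, 0 genes were called between the cytokines, so the fall is not particular to ortho IL-2. Run-on from an upstream gene was argued against as the cause in most members, since 25.3% had such a neighbour upstream and 29.5% downstream (exact McNemar p = 0.644). Genomic DNA stayed open. From ortho IL-2 replicate 3 to no IL-2 replicate 1, the mean of 1300 silent genes rose 6.27-fold, from 0.000652 to 0.00409 RPKM. This rise was 5.31% of what evenly spread DNA would need, but it rests on 1 pair of libraries and very low values. RNA of one other cell type stayed open too, since the spread of ratios of members was 3.21 times that of counting but 2.39 times over all genes, and so did the stimulation alone, since the members, with a range within the ortho IL-2 group 1.45 times the difference between groups, were chosen for varying within groups. Repeats in the transcripts are a candidate explanation, as 74.7% of members held them against 16.1% of other genes (Fisher's exact p = 4.04e-36), and the origin of the repeat reads stayed open.

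Among the 6 stimulated libraries, a split of WT IL-2 replicate 1 and ortho IL-2 replicates 1 and 3 from the others called 4075 genes, and their log2 fold changes followed GC content across genes, which are not independent replicates (Spearman rho 0.819). The 3 libraries set apart were also the deepest, with at least 37497976 reads in genes against at most 33499391 in the others. Unequal counting depth alone was argued against, since 77.9% stayed called with every library thinned to the lowest total of reads in genes. Thinning keeps each gene's share of its library, so it cannot decide on a cause that goes with depth. A stronger stimulation of these libraries stayed open, since 34.6% were called in the direction of both stimulations and 7.71% in the opposite one. Offsets for GC content left 3.91% of the calls with a GC value. Such offsets take out any difference that follows GC content, whatever its cause, so this loss restates the correlation above. GC content is a candidate explanation on that correlation alone. The slope with GC also separated the no IL-2 from the stimulated libraries (two-sided exact permutation p = 0.0357), and since the labels give no batch, what set it stayed open.

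Other splits of the 6 libraries in each comparison number 10 with the real one, too few for a share under 0.05. For WT against no IL-2 the real split called 5122 genes and the highest other 0, and for ortho against no IL-2 5990 and 0, so 1 of 10 splits called as many in each. Between the cytokines the real split called 0 by edgeR and the highest other 4075, so 10 of 10 called as many, as a count of 0 must give. The split that called 4075 genes, described above, points to a structure of these libraries, while 1 of the others called 16 and the rest 0 by edgeR.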
